A study of Caenorhabditis elegans with 4 samples.

How the data were processed

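Binding of the forkhead transcription factor FKH-2 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in Caenorhabditis elegans hermaphrodites at the L3 larval stage. Per the labels, the animals were of strain OP185, which carries a transgene of fkh-2 with a C-terminal EGFP and FLAG tag together with an unc-119 rescue marker. A strain note among the labels once calls the fusion FKH-1, while the genotype and the titles give FKH-2, the name used here. They were grown at 20 °C on HB101 bacteria and crosslinked with 2% formaldehyde, and chromatin was precipitated with antibodies against GFP. The 4 samples were 2 ChIP replicates and 2 input samples of genomic DNA. Groups and replicate numbers came from the sample titles. The titles do not say whether the replicates came from separate cultures, so differences between them may be technical.

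Peak lists of the 2 ChIP replicates and a combined peak list were analysed. No processed values of the input samples were used here. Each replicate list gives, per the file headers and columns, regions whose source is named as spp via IDR, with a deposited score per peak whose scale is not named. Peak names in these lists carry a rank number, and this number was used to rank peaks because it has no ties. The first 611 peaks of replicate 1 and the first 789 of replicate 2 share the highest score of their list, so the order among them comes from the peak names alone. The Spearman correlation of the rank number with the score was -0.999992 in replicate 1 and -0.988349 in replicate 2. Below the ties, rank did not always follow score. In replicate 2, for example, a peak ranked 2795 had a score of 2.90 and one ranked 4244 a score of 2.97. The highest-ranked peaks of that list are therefore not exactly those with the highest scores, and no cut by score was run. The combined list comes from PeakSeq, per the file's source column, with a deposited q-value per peak that was at most 0.00999959. Whether the authors called it on pooled reads or merged it from separate calls is not given in the sources used here. The aligner, the control behind each call and the tool versions are likewise not given in the sources used here. All lists use WormBase WS220 coordinates, per the file headers, and 3 combined peaks carry a comment on a change during coordinate conversion. The sequencing depth of the samples is unknown, so no value below carries a depth.

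Overlap required at least 1 bp. Overlap shares were tested by random placement, in which the peaks of one list on each chromosome were moved by a common random offset and wrapped around the chromosome end. The 10000 placements gave one-sided p-values with a smallest possible value of 1e-04. Random placement keeps the spacing of peaks but ignores mappability and open chromatin, so an excess over it is not specific to FKH-2. The count of combined peaks in 50 kb windows was instead compared with 10000 draws that placed each peak independently and uniformly on its chromosome. For comparisons at equal list length, each replicate list was reduced to its 3378 highest-ranked peaks, the number of combined peaks. Ranks of one-to-one matched peaks were compared by Spearman's rho with 100000 two-sided permutations. Shares of peaks by chromosome were compared with the share of length by two-sided exact binomial tests, with Benjamini-Hochberg adjustment over the 6 nuclear chromosomes. The length of a chromosome was taken as the largest peak end in any list. Intervals of shares are exact Clopper-Pearson 95% intervals and cover counting error only, since peaks are not replicates. Intervals of ratios and distances come from 2000 bootstrap draws.

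The peaks named were the 10 combined peaks with the lowest q and the highest-ranked combined peak of each chromosome, a rule fixed before the data were examined. Regions named outside this rule are said to have been chosen after their values were seen. The alternatives tried were a stricter overlap, a distance limit between midpoints, the higher-ranking 50% of each list, other list lengths, removal of the widest peaks and leaving out each replicate. Leaving out mitochondrial peaks, chromosome I or the densest window was added after seeing the data.

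Annotation and sequence of WS220 were not used here. The gene table at hand belongs to WBcel235, another assembly, so no peak was assigned to a gene. The planned promoter share, enrichment of 13 gene lists, forkhead motif share and motif share by peak rank were therefore not run, and fkh-2, unc-119 and kap-1 are not reported by position.

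The overlap calculation was tested on simulated lists as long as the replicate lists, with 20771 placed peaks. Planted overlaps of 0%, 5% and 20% were recovered as 0.246%, 5.06% and 20.0% after correction for random placement. The correction divided the excess over random placement by the share not overlapped under it. The shares in the results carry no such correction. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.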

Results

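FKH-2 occupancy in L3 larvae was described by 3 peak lists. Replicate 1 had 30000 peaks, nearly all 400 bp wide, which covered 11.5 Mb or 11.5% of the nuclear chromosomes. Whether this round count marks a cut at a fixed list length was not determined. Replicate 2 had 20799 peaks, nearly all 260 bp wide, which covered 5.39 Mb or 5.38%. The combined list had 3378 peaks with a median width of 146 bp and a range of 1 to 9122 bp, and covered 0.585 Mb or 0.584%. Among the combined peaks, 398 (11.8%) were at most 20 bp wide. The q values of this list, as the authors gave them, ran from 1.00e-30 to 0.00999959 with a median of 0.00527.

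The first question was where the combined list had its lowest q values and whether both replicates had peaks there. The 10 combined peaks with the lowest q lay on all 6 nuclear chromosomes, with 3 on X, 2 on III, 2 on V and 1 each on I, II and IV. Each was overlapped by peaks of both replicates, and they were 399 to 1412 bp wide. Peaks this wide are overlapped more easily by chance, and no chance level is given for them here. Replicate ranks given for these sites are the best among the overlapping peaks of that replicate. The best-ranked peaks of the replicates need not overlap each other. The list was headed by V 264907–266012 with q = 1.00e-30, followed by III 10224459–10225356 with q = 1.19e-30 and IV 14032773–14034111 with q = 2.64e-30. The sites III 10224459–10225356 and IV 14032773–14034111 also ranked high in the replicates, at 64 and 19 in replicate 1 and at 23 and 68 in replicate 2. Ranks up to 611 in replicate 1 and up to 789 in replicate 2 order peaks with the same, highest score.

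On X, the site with the lowest q was X 11093796–11094366 (q = 3.37e-20), which held the peak ranked 10 in replicate 1 and 49 in replicate 2. The other X sites in this group were X 14525383–14526367, with q = 3.54e-18 and ranks 30 and 66, and X 8035960–8036936, with q = 5.10e-17 and ranks 180 and 44. On III, the site III 8417157–8417872 had q = 1.68e-21 and ranks 26 and 31. The site with the lowest q on II was II 5543365–5544341, with q = 5.12e-20 and ranks 18 and 285. The site V 14393821–14395232 had q = 7.68e-19 and ranks 764 and 781. Rank and q diverged at a pair of sites. The leading combined peak, V 264907–266012, overlapped peaks ranked only 20426 in replicate 1 and 1987 in replicate 2. The site with the lowest q on I, I 2179751–2180149 with q = 1.09e-21, overlapped peaks ranked 8608 and 2189.

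The ChIP replicates of one condition were compared next. Peaks were shared between the replicates more often than under random placement, although most peaks of either list had no counterpart in the other. In replicate 2, 5401 of 20799 peaks (25.97%) overlapped a replicate 1 peak, against 18.4% (central 95% 17.9 to 18.9) under random placement. In replicate 1, 5760 of 30000 peaks (19.2%) overlapped a replicate 2 peak, against 13.5%. Both excesses had p = 1e-04 by permutation of peak positions (random placement), the smallest value these placements can give. The 3378 highest-ranked peaks stood further above chance, with 473 replicate 2 peaks (14.002%) overlapped by those of replicate 1 against 2.88% under random placement (permutation p = 1e-04, the smallest possible). Among the 3378 highest-ranked nuclear peaks of replicate 1, 465 overlapped one of replicate 2, of which 111 lay on X, 77 on I, 74 on IV, 73 on III, 69 on V and 61 on II.

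Sharing was greatest at the highest ranks. In the highest-ranked decile of replicate 2, 39.6% of peaks (95% interval 37.4 to 41.7) overlapped replicate 1, and in the lowest decile 24.4% did. The corresponding shares of replicate 1 were 34.3% and 15.8%. Across 5299 matched pairs of peaks, the ranks had a Spearman's rho of 0.198 (p = 1e-05, the smallest these permutations can give), and the log scores a Pearson's r of 0.178. This correlation is across peaks of 1 pair of samples, and peaks are not independent replicates.

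**Figure D1:**
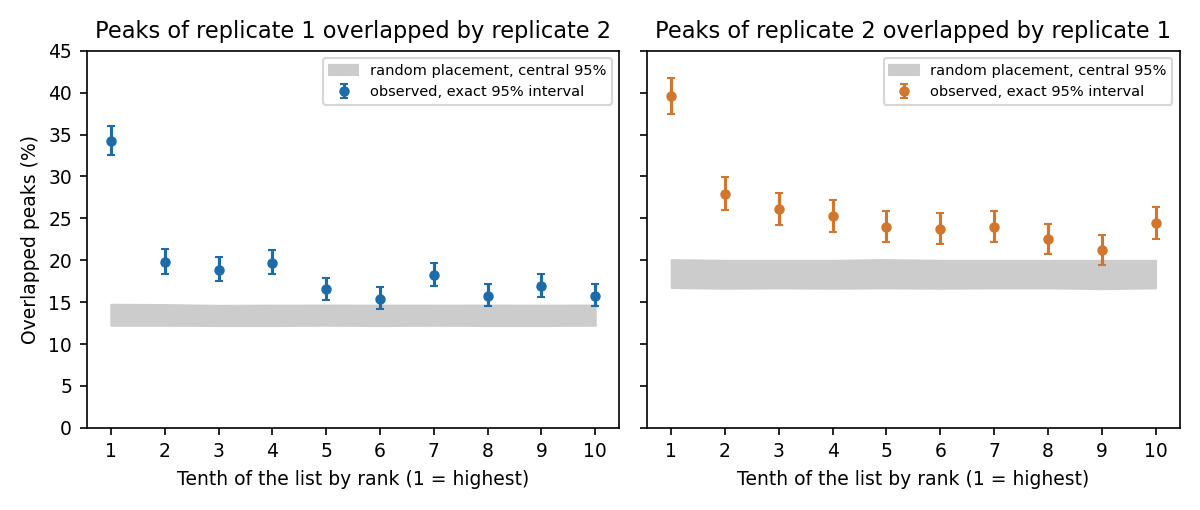
Percent of peaks of each replicate (y axis) that overlapped the other replicate, by decile of rank (x axis, 1 = highest), with points and exact 95% intervals, and the central 95% of random placements as a grey band. The highest-ranked decile reached 34.3% in replicate 1 and 39.6% in replicate 2, against random means of 13.5% and 18.4%.

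The combined peaks were then compared with the replicate lists. Most combined peaks, 2994 of 3378 (88.6%), coincided with a peak of at least 1 replicate, a share not compared with random placement. Overlap with each replicate, and with both, was far more frequent than under random placement. Replicate 1 peaks overlapped 2438 of the 3378 combined peaks (72.2%, against 15.8% under random placement) and replicate 2 peaks 1876 (55.5%, against 8.83%). Both replicates had a peak at 1320 combined peaks (39.1%, against 2.15%). Each excess had a permutation p = 1e-04, the smallest possible. The lists presumably share reads, so an excess was to be foreseen and these p-values are not evidence of binding. Only replicate 1 had a peak at 1118, only replicate 2 at 556, and neither replicate at 384 (11.4%).

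Coverage by both replicates differed between chromosomes. It was 68.9% on I (95% interval 60.3 to 76.7, 132 peaks) and 50.0% on X (45.9 to 54.1, 606 peaks), and lay between 32.6% on IV and 37.1% on III for the other autosomes. Combined peaks without any replicate peak made up 15.5% on IV (12.9 to 18.3), 8.25% on X (6.19 to 10.7) and 4.55% on I (1.69 to 9.63, 6 of 132), and 11.1% to 11.6% on II, III and V. In tests chosen after these shares were seen, replicate 1 covered 87.1% of combined peaks on I against 71.6% elsewhere (Fisher exact p = 4.07e-05), and replicate 2 covered 77.3% against 54.7% (p = 1.49e-07 by the same exact test). Combined peaks were also wider on I, with a median of 250.5 bp against 141.5 bp elsewhere, and the median on X was 178.5 bp. With I left out, X held 24.7% of the peaks covered by both replicates and 15.02% of the others (Fisher exact p = 1.86e-11). Coverage also followed the q value. In the decile with the lowest q, 84.0% of combined peaks (79.7 to 87.8) were covered by both replicates and the median width was 376 bp. In the decile with the highest q, 15.7% (12.01 to 20.06) were covered and the median width was 58 bp. Wider peaks are overlapped more easily, and the lists presumably share reads, so these shares are not independent evidence of binding.

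**Figure D2:**
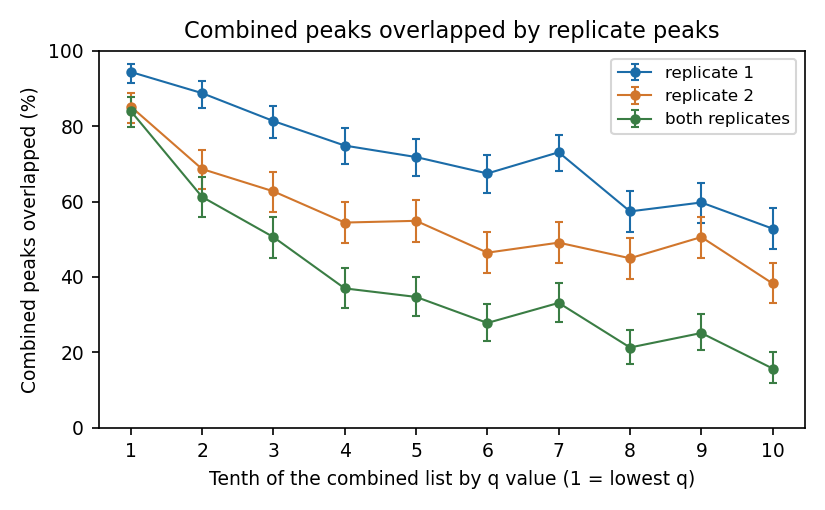
Percent of combined peaks (y axis) overlapped by replicate 1, by replicate 2 and by both, by decile of the q value (x axis, 1 = lowest q), with exact 95% intervals. Coverage by both replicates was 84.0% in the first decile and 15.7% in the last.

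The distribution over chromosomes addressed whether binding was spread in proportion to length. Combined peaks were densest on III, at 43.8 per Mb (95% interval 40.62 to 47.02, 603 peaks), and on IV, at 41.4 per Mb (38.7 to 44.1, 724 peaks). Chromosome V had 36.4 per Mb, II had 36.1 and X had 34.2. Chromosome I had 8.76 per Mb (7.36 to 10.4, 132 peaks). In the 3378 highest-ranked nuclear peaks of each replicate, chromosome I lay much closer to the other chromosomes, with 30.1 per Mb in replicate 1 and 33.9 per Mb in replicate 2, and X was dense in both, with 41.0 and 40.4 per Mb. Chromosome IV was the least dense in both, with 27.4 and 30.5 per Mb.

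The planned test of X found 606 of 3378 combined peaks there (17.9%, 95% interval 16.7 to 19.3) against 17.7% of the length (exact binomial p = 0.668). X held 21.5% of the highest-ranked replicate 1 peaks (exact binomial p = 1.27e-08), 21.2% of those of replicate 2 (p = 1.44e-07) and 22.95% (20.7 to 25.3) of the combined peaks covered by both replicates (p = 1.06e-06). Tested after its count had been seen, chromosome I held 3.91% of combined peaks (3.28 to 4.62) against 15.03% of the length (adjusted exact binomial p = 3.49e-97). Its share was 13.4% (12.3 to 14.6) in the highest-ranked peaks of replicate 1, also below its share of length (adjusted exact binomial p = 0.01196), and 15.1% in those of replicate 2 (p = 0.904). The shares of one list sum to the whole, so the low count on I raised those of the other chromosomes in the combined list. Adjusted exact binomial p-values were 7.09e-11 for III, 5.53e-09 for IV, 0.0282 for V and 0.0918 for II. III held 16.7% of the highest-ranked peaks in replicate 1 (adjusted exact binomial p = 3.16e-06) and 14.4% in replicate 2 (p = 0.339), against 13.7% of the length. IV (21.4%) and V (22.5%) lay above their share of length in the combined list and below it in the replicate lists. Whether either excess remains with chromosome I left out was not tested. IV, with 17.5% of the length, held 14.2% of the highest-ranked peaks in replicate 1 (adjusted exact binomial p = 8.86e-07) and 15.8% in replicate 2 (p = 0.0249). V, with 20.9% of the length, held 18.6% (adjusted exact binomial p = 0.00154) and 19.1% (p = 0.0249). Among combined peaks covered by both replicates, IV held 17.9% (adjusted exact binomial p = 0.828) and V 20.6% (p = 0.839). Without chromosome I, a setting chosen after seeing the data, the X share of the combined list turned from slightly above to below its share of length, with 18.7% against 20.8% (exact binomial p = 0.00283).

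**Figure D3:**
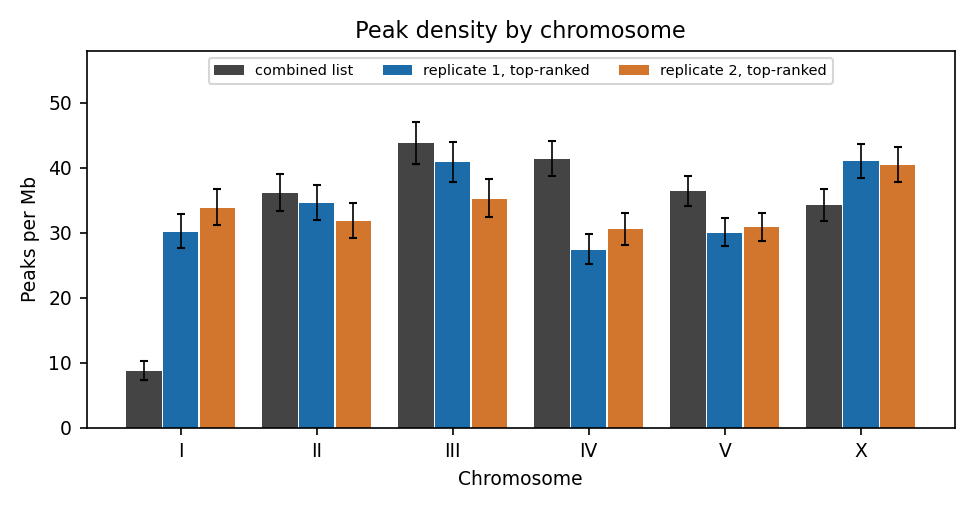
Peaks per Mb (y axis) on each nuclear chromosome (x axis) in the combined list and in the 3378 highest-ranked nuclear peaks of each replicate, with bars for the density and lines for exact 95% intervals. Chromosome I had 8.76 combined peaks per Mb against 30.1 and 33.9 in the replicates, and X had 34.2 against 41.0 and 40.4.

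Autosome centres, which are rich in conserved and highly expressed genes in C. elegans, were compared with the arms. The third of each autosome at its centre held 1046 of 2772 combined peaks (37.7%, 95% interval 35.9 to 39.6) against 33.3% of the length (exact binomial p = 1.18e-06). The central share was 39.4% on V (35.9 to 43.0), 39.3% on III (35.4 to 43.3), 37.5% on II (33.4 to 41.7), 36.4% on I (28.2 to 45.2) and 35.1% on IV (31.6 to 38.7). The interval of a single autosome excluded 33.3% on II, III and V and included it on I and IV. On X, which was not part of the test, the central share was 31.7% (28.0 to 35.6). In the complete replicate lists, the central share of the autosomes ran from 34.1% on V to 35.3% on IV in replicate 1. In replicate 2 it ran from 36.3% on V to 37.4% on IV, so a central excess was not particular to the combined peaks. The test does not take mappability into account.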

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

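The count of mitochondrial peaks was made after the lists had been seen, and no explanation for it was tested. This signal stands out because it lies outside the main measurement. The comparisons of chromosomes concern the nuclear chromosomes, yet both replicate lists also held mitochondrial peaks, with 24 in replicate 1 and 28 in replicate 2. Mitochondrial peaks took 9 of the 10 highest ranks in replicate 1 and 10 of 10 in replicate 2, and 17 and 23 of the 50 highest. The combined list had 0 mitochondrial peaks. In replicate 1, 11 peaks repeated the coordinates of another peak.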

How the results depend on the processing

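The chromosome I share and every setting without mitochondrial peaks, chromosome I or the densest window were chosen after the result was seen. The replicate overlap share, the overlap of the highest-ranked peaks, coverage by both replicates, the rank correlation and the central share of the autosomes kept their direction and their side of the threshold in every alternative run. Their sizes moved: with midpoints within 100 bp the replicate overlap was 10.8% and that of the highest-ranked peaks 8.91%. Coverage by both replicates was 25.6% with the higher-ranking 50% of each replicate list. At combined peaks Spearman's rho was 0.221 and Pearson's r 0.107, against 0.198 and 0.178 across all matched pairs. With the stricter overlap rho was 0.235 and r 0.204. The share of X did not pass its test in the combined list, and with either replicate left out (the list of the other, reduced to 3378 peaks) it lay between 21.2% and 21.5% and passed. Without chromosome I the X share was 18.7% and its direction turned, because the expected share rose to 20.8%. The chromosome I share lay between 13.4% and 15.1% with either replicate left out. At 13.4%, in the list of replicate 1, it was still below length (exact binomial p = 0.00997). At 15.1%, in the list of replicate 2, its difference from the 15.03% of length did not pass the test (exact binomial p = 0.904) and lay marginally on the other side; the cause was not tested here. No paired analysis was possible because no processed values of the input samples were analysed here. Promoter share, gene list enrichment, forkhead motif share and motif share by peak rank were not run for lack of annotation and sequence of the same build. Unknown depth limits every comparison of list lengths.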

Other observations

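All regions in the next 2 paragraphs were chosen after their values were seen, as were the tests of few bound sites on chromosome I, the odds ratios for weaker peaks there and both tests of the X share.

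Nuclear sites ranked among the first 300 in both replicates numbered 74, and all 74 overlapped a combined peak. X held 22 of them, III 14, II 12, V 10, IV 9 and I 7. The midpoints of the paired peaks lay a median of 49 bp apart. Beyond the sites already named, II 12102369–12102768 ranked 16 and 17 with q = 9.04e-16, and II 8787277–8787676 ranked 31 and 12 with q = 2.72e-14. The site IV 5593835–5594234 ranked 22 and 21 with q = 5.27e-17, and X 6296383–6296782 ranked 23 and 29 with q = 1.34e-11. Coordinates here are those of the replicate 1 peaks. All of these ranks lie among peaks tied at the highest score, 611 in replicate 1 and 789 in replicate 2.

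Combined peaks were clustered in a few places. The 50 kb window V 14350000–14399999 held 22 combined peaks, against a median of 1 per window on V, more than in any of 10000 draws that placed each combined peak independently and uniformly on its chromosome (highest 15, permutation p = 1e-04, the smallest possible). These peaks spanned V 14363035–14395232, and 7 of them had a q below 1e-06. The uniform draws did not keep the spacing of peaks, and whether neighbouring calls belong to 1 enriched stretch was not tested. Their p-value is therefore not evidence of separate sites. The same window held 49 replicate 1 peaks (median 14) and 39 replicate 2 peaks (median 10). The window X 11450000–11499999 held 13 combined peaks against a median of 2. The widest combined peaks were X 3737607–3746728 (9122 bp, q = 8.58e-04) and X 3747976–3752149 (4174 bp, q = 1.90e-11). Neither replicate list had a peak anywhere in the surrounding X 3722533–3754992, a stretch of 32460 bp, and only 10 of 41992 gaps between replicate peaks were at least as long. The strain carries a transgene with fkh-2 and unc-119 sequence, and whether these X peaks lie in such sequence was not determined, so their widths and q values are not read as binding.

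The first pattern weighed was the low number of combined peaks on chromosome I (3.91%). Few bound sites there in the animals would also have lowered its share in each replicate. The lower replicate share was 13.4% (lower end of its 95% interval 12.3%). Most of these peaks had no counterpart in the other replicate, so background peaks could hide a low share. Among the 465 peaks shared by the replicates, chromosome I held 16.6% (13.3 to 20.3). This argues against few bound sites, so far as sharing marks binding. A loss of weaker peaks stays open: recovery in the combined list on chromosome I relative to elsewhere was 2.15 times higher (1.60 to 2.97) for replicate ranks 1 to 300 than for ranks above 1000 among the first 3378, but recovery elsewhere was near its ceiling at the high ranks (90.02% against 22.4%). On the odds scale the difference ran the other way, with odds ratios of 0.207 and 0.282, and their ratio of 0.734 (0.412 to 1.38) did not exclude 1. High-ranked peaks were affected too, since 65.1% of peaks ranked 1 to 300 in a replicate were recovered on I against 90.02% elsewhere. Of the peaks shared by the replicates among their first 3378, 57.1% were recovered there against 89.4% elsewhere (odds ratio 0.158). However, all 7 sites on I ranked among the first 300 in both replicates were recovered. Chromosome I held 4.14% of the 1689 combined peaks with the lowest q, but q comes from the same call. Reads of 1 replicate missing for chromosome I would lower recovery on one side, whereas recovery relative to elsewhere was low for peaks found only in replicate 1 (0.254, 0.143 to 0.378) and only in replicate 2 (0.175, 0.0518 to 0.308), and both replicates covered more of the combined peaks on I (87.1% against 71.6% and 77.3% against 54.7%), but the factor of 1.45 (0.641 to 4.75) between these recoveries, from 17 and 7 peaks, does not exclude it.

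The second pattern was the small overlap of the replicate lists. A shift between their peak positions would move midpoints apart in one direction, and the median signed distance of 5 bp (-1 to 10) over 5010 pairs within 300 bp argues against it. For lower-ranked peaks near the chance level, the limits set before were under 5 percentage points over random placement in the lowest-ranked quintile and over 10 in the highest. The lowest-ranked quintile of replicate 2 overlapped replicate 1 by 4.52 points over random placement (3.25 to 5.83). The point values met both limits. The explanation stays open because this interval lies on both sides of 5 points, a condition those limits did not include. The highest-ranked quintile lay 15.4 points over random placement. By decile, the lowest-ranked ones, 9 and 10, lay 2.96 and 6.09 points over random placement in replicate 2. In replicate 1, for which no limit was set, deciles 9 and 10 lay 3.50 and 2.35 points over it, and decile 1 lay 20.8 points over it. No biological explanation was tested, since both replicates belong to 1 group.

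The third pattern was the lower X share of the combined list than of the highest-ranked replicate peaks. The low count on chromosome I in the denominator does not account for it, since without that chromosome X held 18.7% of combined peaks (17.3 to 20.1) against 24.83% and 24.97% in the replicates. Combined peaks without any replicate peak do not account for it alone, as leaving them out as well gave 19.4% (17.95 to 20.88). Without chromosome I, X held 24.7% of the combined peaks covered by both replicates, 15.4% of those covered by 1 replicate and 13.2% of those covered by neither. No biological explanation was tested. The combined list comes from PeakSeq and the replicate lists name spp via IDR, so differences between lists cannot be told apart from differences between callers. This holds for chromosome I as well as for X, and why the lists differ stays open.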
